A study of Mus musculus with 9 samples.

How the data were processed

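Messenger RNA was sequenced from mouse liver of the Balb/c strain, taken at 9 weeks of age. The labels give 3 groups with 3 livers each, named vehicle, APAP and LRH1+APAP, and each of the 9 libraries is 1 liver. APAP is acetaminophen, and LRH1 is the nuclear receptor encoded by Nr5a2. According to the labels, tissue was kept in RNAlater, total RNA was extracted with Trizol, and libraries were prepared from 1 µg of total RNA with the Illumina TruSeq mRNA kit. Dose, route, time between treatment and collection, sex, and the means by which LRH1 was given are not given in the sources used here. There was no group that received LRH1 without APAP. The series text names LRH1 where the sample labels say LRH1+APAP, and the sample labels were followed.

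The values analysed were the deposited FPKM of the authors, fragments per kilobase of transcript per 1e6 mapped fragments, with 1 column per library on genome build mm10. The submitters' processing notes list FastQC 0.10.0, Bowtie2 2.2.6 and StringTie 1.3.3b without a role or an order. No scaling between libraries is stated. The deposited values covered 36779 transcript models under 24541 gene symbols, and FPKM was summed over the models of each symbol. Column names were matched to livers through the sample descriptions, which left 0 columns without a sample. Transcript start positions were 1 above the annotation for 7774 of the 14033 transcripts whose end matched it, so the start positions are those given with the values.

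Read counts were not analysed here, and the number of reads per library is unknown. Summed FPKM ranged from 520072 to 575365 per library. In genes with a single transcript, low values multiplied by length rose in steps that would correspond to a depth of 23.9 to 37.5 in units of 1e6 fragments per library. Between 47.1 and 53.1 percent of those values lay within 0.05 of a whole step, so whole reads were not recovered and no counting intervals are given. Precision was taken from the spread between livers.

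Genes with a mean of at least 0.5 FPKM over the 9 libraries were tested, which kept 12202. Values were transformed as log2 of FPKM plus 1. One linear model with a mean for each group was fitted to the 9 libraries with limma 3.58.1 in R 4.3.3, with moderated variances and an intensity trend, leaving 6 residual degrees of freedom. The 3 contrasts were APAP against vehicle, LRH1+APAP against APAP, and LRH1+APAP against vehicle. Tests were two-sided, adjusted p-values are Benjamini-Hochberg values over the genes tested, and a gene passed at an adjusted p under 0.05. Fold changes are on the log2 scale of FPKM plus 1 unless a ratio of mean FPKM is named. Data were read with the R package data.table, version 1.17.8, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

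Gene lists numbered 38 and were written from textbook knowledge of liver and of acetaminophen injury. The 34 lists with at least 5 tested members were tested with camera in limma, at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance without comparing them to other genes, were run as alternatives. Members that pass with p-values adjusted over the list alone are counted beside those that pass over all genes. Lists of snoRNA host genes, SRF and YAP targets and glucocorticoid targets were written later, to test patterns found in the data. Of the glucocorticoid targets, 6 of 15 were also in the lists written first and had been looked at there. Lists overlap in places, so a gene can count in more than 1 of them.

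The LRH1+APAP against APAP contrast shares its APAP livers with the APAP against vehicle contrast, which gives opposite signs without any effect of LRH1. The share of genes with opposite signs was therefore set beside 100 simulated data sets in which the LRH1+APAP group was an unchanged redraw of the APAP group. The APAP livers were too few to be divided between the contrasts.

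Groups, contrasts, the limma and camera tests of genes and lists, the 38 gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The exceptions among the alternatives are those that left out transcript models under 200 bases (1573 of them) or repeated loci of a transcript (947 of them). The rule for named genes took Nr5a2 first. It then took the 5 largest rises and the 5 largest falls among genes that passed, with a mean of at least 5 FPKM in the higher group and no overlap between groups, passing over symbols of the Gm and Rik kind. It added the 3 members with the smallest p in each of the 10 called lists of smallest p, and a fixed panel of liver and injury genes. For LRH1+APAP against vehicle it took 3 genes in each direction and the panel genes whose call differed from that of APAP against vehicle. Results for some genes that this rule took are not reported here. Other list members appear as examples of their list and were chosen after their values were seen. Values for genes of families with similar copies, such as Cyp2a, Cyp2c, Gsta, Gstm, Hba, Hbb, Hspa1 and Mup, are uncertain for the single gene, because similar copies share reads.

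Alternatives changed the pseudocount, the filter on low values, the scaling (TPM, upper quartile, quantile normalization), the weights, the libraries in the fit, the level of testing and the fold required, and left out each liver in turn. The model was tested on simulated data with independent noise, at each gene's spread pooled over the groups. It recovered 82 to 84 percent of genes changed by 1 on the log2 scale, depending on the contrast. It recovered 93 to 98 percent of those changed by 2, with 3.8 to 9.64 percent of calls false. The simulation left out correlation between genes and the larger spread of the APAP livers. Its shares therefore do not give the error of the real contrasts. The labels do not say that the livers of a group come from separate animals. The p-values measure only the spread between these samples, which may be technical. With 3 livers against 3, an exact permutation test of a single gene cannot give a two-sided p below 0.1, so none was used.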

Results

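Liver messenger RNA was measured in 3 groups of 3 livers. The vehicle group received vehicle, the APAP group received acetaminophen, which hepatocytes turn into a reactive and toxic metabolite, and the LRH1+APAP group received acetaminophen together with LRH1, a nuclear receptor of hepatocytes encoded by Nr5a2. Summed FPKM was 555202, 575365 and 565311 in vehicle livers 1 to 3, 555936, 551806 and 546381 in APAP livers 1 to 3, and 521263, 529493 and 520072 in LRH1+APAP livers 1 to 3. Genes above 1 FPKM numbered 10211 to 10368 in vehicle livers, 10926 to 11207 in APAP livers and 10986 to 11104 in LRH1+APAP livers. The 100 genes of highest mean in vehicle livers held 54.1 to 55.12 percent of the FPKM of vehicle livers, 43.38 to 46.99 percent in APAP livers and 42.47 to 45.48 percent in LRH1+APAP livers. Livers of a group resembled each other least in the APAP group. Spearman correlations between livers, computed across genes, which are not independent replicates, were 0.9899 to 0.9904 among vehicle livers, 0.9491 to 0.9768 among APAP livers and 0.9887 to 0.9908 among LRH1+APAP livers. APAP liver 1 stood as close to the LRH1+APAP livers as to its own group. Its Spearman correlations were 0.98, 0.9756 and 0.9741 with LRH1+APAP livers 1 to 3, and 0.9491 and 0.9755 with APAP livers 2 and 3. The root mean square SD of the log2 values was 0.178 in vehicle, 0.312 in APAP and 0.177 in LRH1+APAP livers.

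**Figure D1:**
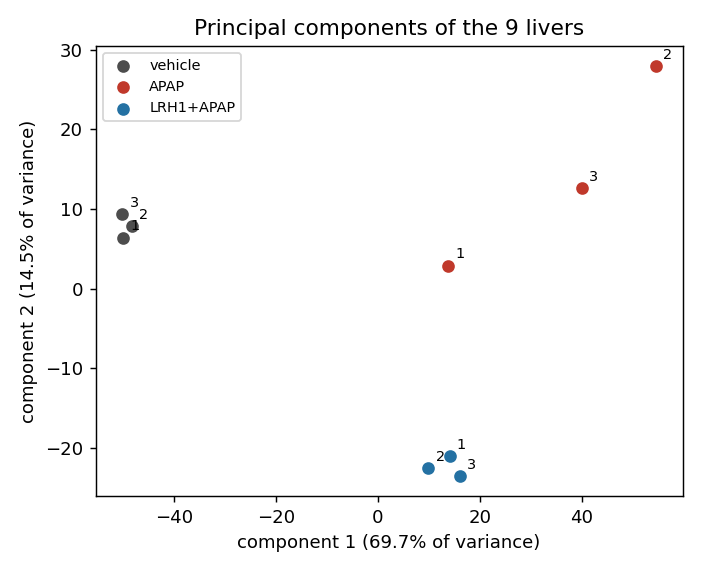
Principal components of log2(FPKM + 1) over the tested genes, with component 1 (69.7 percent of the variance) on the x axis and component 2 (14.5 percent) on the y axis, and 1 numbered point per liver coloured by group. The vehicle livers lie between -50.2 and -48.3 on component 1, the APAP livers spread from 13.8 (liver 1) to 54.6 (liver 2), and the LRH1+APAP livers lie between 9.9 and 16.1 and are separated from the APAP livers on component 2.

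The comparison of APAP with vehicle shows what the drug did to the liver transcriptome. Many genes of hepatocyte function fell, among them genes of the cells around the central vein. Cyp2e1, the cytochrome P450 that forms the toxic metabolite of acetaminophen (chromosome 7, 140763833 to 140774977), went from 8373 ± 426.1 to 2009 ± 390.8 FPKM (mean ± SD, n = 3). Glul, the glutamine synthetase of the innermost pericentral hepatocytes (chromosome 1, 153899930 to 153909723), went from 173.3 ± 17.2 to 28.7 ± 4.65 FPKM (n = 3). Stress genes rose at the same time. Hmox1, the heme oxygenase induced by oxidative stress (chromosome 8, 75093619 to 75100593), went from 10.7 ± 1.66 to 233.2 ± 52.9 FPKM, and Ddit3, a transcription factor of the endoplasmic reticulum stress response (chromosome 10, 127290794 to 127296288), from 7.52 ± 2.66 to 216.5 ± 63.2 FPKM (n = 3).

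Of the 12202 genes tested with limma, 5835 were higher and 1845 lower in APAP livers, and 1207 of the higher and 355 of the lower changed by at least 2-fold. Nr5a2 (chromosome 1, 136843585 to 136960448) was listed at 14.7, 13.1 and 12.3 FPKM in vehicle livers and at 10.8, 9.29 and 10.3 FPKM in APAP livers (log2 difference -0.37, adjusted p = 0.257). It passed with 6 libraries in the fit (adjusted p = 0.0207), and its alternatives ranged from 0.0207 to 0.442. The 5 largest rises were in Egr1, Atf3, Jun, Sprr1a and Hspa1a. Egr1, an immediate early transcription factor, rose from 0.871 ± 0.125 to 615.0 ± 23.3 FPKM (log2 8.36, adjusted p = 2.95e-08, n = 3). The stress-induced transcription factors Atf3 and Jun rose by 8.13 and 7.30 (adjusted p = 2.95e-08 and 7.11e-07). Sprr1a, a squamous envelope protein that other injured tissues also express, passed the test with values of 78.5, 169.0 and 197.2 FPKM in APAP livers and was listed at 0 in each vehicle liver. Hspa1a, an inducible heat shock protein, rose by 6.52 (adjusted p = 1.52e-05). The 5 largest falls were in Mup18, Upp2, Cyp2c39, Cyp2c38 and Cyp2a5. Mup18, a major urinary protein, fell by 6.03 (adjusted p = 0.000533) and Upp2, a uridine phosphorylase, by 5.03 (adjusted p = 4.51e-05). The cytochrome P450 genes Cyp2c39, Cyp2c38 and Cyp2a5 fell by 5.01, 4.49 and 4.10 (adjusted p = 4.83e-06, 7.11e-07 and 8.52e-05).

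Pericentral genes and drug metabolism fell together. Of 16 tested pericentral genes, 14 fell and 0 rose, as they did adjusted over the list alone, with a median of -1.42 (camera adjusted p = 1.02e-13, adjusted p = 0.318 with an estimated correlation). Rgn, regucalcin, and Oat, ornithine aminotransferase, fell by 2.07 and 1.88, beside Glul at -2.56. The cytochrome P450 list also held Por, the reductase of these enzymes. Of 20 genes in that list, 18 fell and 0 rose (19 and 0 adjusted over the list alone, camera adjusted p = 6.05e-14, adjusted p = 0.232 with an estimated correlation). Among them were Cyp2c54, Cyp2c50 and Cyp2e1 at -2.47, -2.17 and -2.07. Conjugation and transport had 18 genes, of which 13 fell and 1 rose, the same counts as those adjusted over the list alone (camera adjusted p = 4.13e-09, adjusted p = 0.321 with an estimated correlation). Ugt1a1, which glucuronidates bilirubin, and the sulfotransferase gene Sult2a8 fell by 1.24 and 1.65, while Gstp1, a glutathione transferase, was the 1 that rose. Of 14 genes of bile acid synthesis and transport, 10 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 5.14e-06, adjusted p = 0.334 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265613 to 6275631), fell from 35.8 ± 15.2 to 1.70 ± 0.542 FPKM (log2 -3.69, adjusted p = 0.000172, n = 3), and Akr1d1 and Cyp27a1, other enzymes of the pathway, fell by 2.93 and 0.94.

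Lists of amino acid, sugar and fatty acid metabolism also fell. Of 18 genes of the urea cycle and amino acid catabolism, 13 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 2.58e-09, adjusted p = 0.321 with an estimated correlation). Tat, tyrosine aminotransferase, fell by 1.84, while the urea cycle gene Ass1 was listed at only 0.681 ± 0.0698 FPKM in vehicle livers (n = 3), a value too low for this abundant liver enzyme to be taken as its true level. Of 15 genes of gluconeogenesis and glycolysis, 9 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.000183, adjusted p = 0.232 with an estimated correlation). Pck1, which drives glucose production, and the glucose transporter gene Slc2a2 fell by 1.48 and 1.79, and the 3 that rose were Slc2a1, Pkm and Ldha, which act in glucose uptake and glycolysis. Fatty acid oxidation and ketogenesis had 18 genes, of which 8 fell and 1, the pyruvate dehydrogenase kinase gene Pdk4, rose by 3.61 (5 and 1 adjusted over the list alone; camera adjusted p = 8.34e-05, adjusted p = 0.412 with an estimated correlation, fry adjusted p = 0.131). Without vehicle liver 2 or 3, 4 of these genes fell, and without APAP liver 2, 5 fell. Of 14 genes of fatty acid synthesis, 6 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.00775, adjusted p = 0.339 with an estimated correlation; 0.0726 after quantile normalization). Of 20 nuclear genes of the mitochondrial respiratory chain, 11 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 5.28e-06, adjusted p = 0.404 with an estimated correlation), with Ndufs1, Sdha and Sdhb at -0.57, -0.50 and -0.54. The count was 7, 5 and 7 without vehicle livers 1, 2 and 3 and 6 without APAP liver 2 or 3.

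Lists of hepatocyte identity held genes that fell and genes that rose. Of 22 hepatocyte transcription factors, 10 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.000527, adjusted p = 0.348 with an estimated correlation, fry adjusted p = 0.108), and 6 fell without vehicle liver 3. The drug-sensing receptors Nr1i2 and Nr1i3 fell by 1.08 and 1.26, and Zfp36l1, which was in the list although it is an RNA-binding protein that degrades messages, rose by 1.48. Hnf4a, a central hepatocyte factor, fell by 0.26 (adjusted p = 0.0262). That call was lost without vehicle liver 3 (adjusted p = 0.0885), APAP liver 2 (0.0669) or APAP liver 3 (0.0564), after quantile normalization (0.0871) and with 6 libraries in the fit (0.059), with a range of 0.00211 to 0.0885 over its alternatives. Of 15 LRH1 target genes, 10 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.000372, adjusted p = 0.232 with an estimated correlation; 0.0816 after quantile normalization). Cyp8b1, which sets the share of cholic acid, fell by 1.05 (adjusted p = 0.00308). Nr0b2, the bile acid-responsive repressor SHP, fell by 1.18 (adjusted p = 0.0411), a call lost without vehicle liver 1, 2 or 3 (adjusted p = 0.0769, 0.128 and 0.0565) and with 6 libraries in the fit (0.0802), with a range of 0.0174 to 0.128 over its alternatives. Of 20 hepatocyte secreted protein genes, 7 rose and 7 fell, also adjusted over the list alone, with a median of 0.03 and a downward camera direction (adjusted p = 0.0716). After upper-quartile scaling their median was -0.24, with 1 that rose and 11 that fell, and without vehicle liver 2, APAP liver 2 or APAP liver 3 the counts were 4 and 4, 6 and 4, and 4 and 5. The list passed without vehicle liver 2 (0.0439) or APAP liver 1 (0.0488). Alb, albumin, was listed at 35320 and 29780 FPKM (log2 -0.24, adjusted p = 0.073), but passed as lower after upper-quartile scaling (-0.52, 0.00617) and stood at 0.20 after quantile normalization (0.289). Cebpa, another hepatocyte factor, was listed at 86.8 ± 59.6 and 89.4 ± 35.9 FPKM, with an erratic spread over its 5 transcript models. The bile acid receptor gene Nr1h4 stood at -0.55 (adjusted p = 0.231), and without APAP liver 1 at -0.95 (0.0239).

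Further hepatocyte lists fell with them. Of 20 genes of complement and coagulation, 11 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 5.14e-06, adjusted p = 0.339 with an estimated correlation). The clotting factors F9 and F5 fell by 0.88 and 0.84, and C5ar1, a complement receptor of leukocytes, rose by 1.41. Of 16 periportal genes, which mark hepatocytes near the portal vein, 8 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.00304, adjusted p = 0.339 with an estimated correlation, fry adjusted p = 0.0966; 0.128 after quantile normalization). Of 13 genes with sex-biased expression in liver, 8 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.000372, adjusted p = 0.339 with an estimated correlation; 0.107 after quantile normalization), and 1 rose without vehicle liver 3. Of 14 circadian clock genes, 6 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.0238, adjusted p = 0.348 with an estimated correlation, fry adjusted p = 0.728). The clock call was lost after upper-quartile scaling (0.119), after quantile normalization (0.212), among genes with a mean of at least 5 FPKM (0.0696) and without vehicle liver 3 (0.0517). The core activator Arntl and the repressor Nr1d1 rose by 2.25 and 2.68, while Per2, Per3 and Dbp fell by 1.73, 2.26 and 2.00.

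Stress and damage lists rose. Of 12 heat shock genes, 12 rose, also adjusted over the list alone (camera adjusted p = 3.22e-06, adjusted p = 0.334 with an estimated correlation), among them Bag3, Hspb1 and Hsp90aa1 by 4.94, 3.52 and 2.57. Of 15 immediate early genes, 15 rose, also adjusted over the list alone (camera adjusted p = 2.17e-05, adjusted p = 0.348 with an estimated correlation), Klf6 by 4.51. Among 18 genes of the integrated stress and unfolded protein response, 14 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00164, adjusted p = 0.339 with an estimated correlation). Of 20 NRF2 and glutathione genes, 13 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0238, adjusted p = 0.412 with an estimated correlation; 0.0578 among genes with a mean of at least 5 FPKM). Of 14 p53 targets, 11 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0238, adjusted p = 0.339 with an estimated correlation; 0.0546 among genes with a mean of at least 5 FPKM). Cdkn1a, a cell cycle inhibitor induced by p53, rose from 1.79 ± 1.17 to 65.3 ± 26.4 FPKM (n = 3). Of 20 ribosomal protein genes, 20 rose, also adjusted over the list alone (camera adjusted p = 5.28e-06, adjusted p = 0.339 with an estimated correlation), by a median of 0.57, with Rpl10a at 0.79. After upper-quartile scaling, 18 of the 20 rose, by a median of 0.30.

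Many markers of other cell types were higher too, but so were 5835 of all 12202 genes tested, with a median of 0.25 over all genes. Counts of rises in lists that did not pass camera are to be read beside that share. Of 13 monocyte and macrophage markers, 11 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 0.0118, adjusted p = 0.412 with an estimated correlation; 0.0769 among genes with a mean of at least 5 FPKM). Of 12 cytokine and chemokine genes, 11 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0201, adjusted p = 0.437 with an estimated correlation), Ccl2 by 2.93. The other such lists did not pass as lists. Of 8 neutrophil markers, 7 rose (8 adjusted over the list alone; camera adjusted p = 0.139), and 4 rose without vehicle liver 1, 2 or 3, while the list passed without APAP liver 2 (0.00576). Of 10 Kupffer cell markers, 7 rose (7 adjusted over the list alone, adjusted p = 0.177), and of 14 endothelial markers, 10 rose (10 adjusted over the list alone, adjusted p = 0.0975, and 0.0111 without APAP liver 2). Of 15 stellate cell and fibroblast markers, 7 rose (7 adjusted over the list alone, adjusted p = 0.124), and without APAP liver 2, 11 rose and the list passed (adjusted p = 0.0463). Of 5 cholangiocyte markers, 3 rose (3 adjusted over the list alone, adjusted p = 0.487), and of 7 erythroid markers, 4 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.918). Too few markers of some cells were expressed for a list test. Both tested T, B and NK cell markers rose (2 adjusted over all genes, of 14 listed), as did 2 of 3 tested metallothioneins and the adipocyte marker Fabp4, the 1 tested of 6. The 1 tested pancreatic acinar marker of 10, Cela1, was listed at 8.56 ± 0.857 and 7.41 ± 1.55 FPKM (n = 3) and did not pass.

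The remaining lists did not pass in this comparison. Of 18 acute phase genes, 7 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.938), with a median of 0.46 against a downward camera direction, and 4 rose without APAP liver 3. Saa1, serum amyloid A, was listed at 45.1 ± 19.5 and 38.0 ± 18.4 FPKM (adjusted p = 0.667, n = 3). Of 18 interferon response genes, 9 rose (8 adjusted over the list alone, adjusted p = 0.938), and 4 and 5 rose without vehicle liver 1 and APAP liver 3. Of 14 cell cycle genes, 10 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.189), including Ccnd1, cyclin D1, by 2.05. Of 18 cholesterol synthesis genes, 5 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.181), with a median of 0.29 against a downward camera direction, with 10 that rose without APAP liver 1 and a call without APAP liver 2 (0.0445).

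In each of the 3 comparisons, 0 camera calls held with an estimated correlation. The smallest such adjusted p was 0.232 for APAP against vehicle, 0.497 for LRH1+APAP against APAP and 0.264 for LRH1+APAP against vehicle, where camera with the preset correlation called 23, 12 and 22 of 34 lists and fry called 25, 8 and 22. The excess of higher genes depended on scaling. Higher genes were 76.0 percent of the calls for APAP against vehicle as deposited, 54.1 percent after upper-quartile scaling and 46.4 percent after quantile normalization, as the median difference over all genes went from 0.25 to 0.04 and -0.04.

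The comparison of LRH1+APAP with APAP holds the drug constant and asks what differed in livers that also received LRH1. How LRH1 was given is not known here, so LRH1 and its delivery cannot be told apart. Nr5a2, which encodes LRH1, was listed at 205.7, 83.8 and 113.4 FPKM in the LRH1+APAP livers and at 10.8, 9.29 and 10.3 FPKM in the APAP livers. The mean was 13.2-fold higher (134.3 ± 63.6 against 10.1 ± 0.778 FPKM, n = 3), a log2 rise of 3.50 with an SE of 0.27 (adjusted p = 0.00102), and both of its transcript models were higher. Pericentral and drug-metabolising genes that had fallen with APAP were higher again. Cyp7a1 rose from 1.70 ± 0.542 to 64.4 ± 25.9 FPKM and Glul from 28.7 ± 4.65 to 132.9 ± 16.5 FPKM (n = 3). The stress genes Hmox1 and Ddit3 rose further, to 503.8 ± 83.2 and 502.3 ± 58.0 FPKM (n = 3).

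**Figure D2:**
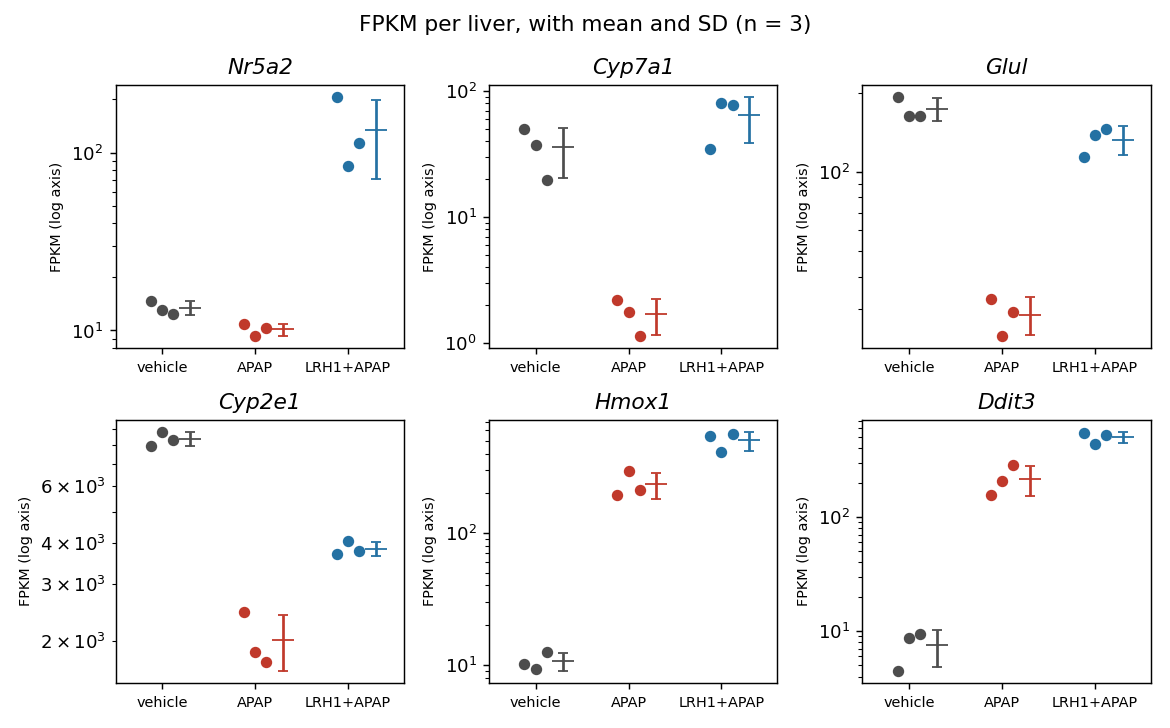
FPKM on a log axis for Nr5a2, Cyp7a1, Glul, Cyp2e1, Hmox1 and Ddit3 in vehicle, APAP and LRH1+APAP livers, with 1 point per liver and a bar for the mean and SD (n = 3). Nr5a2 is high in the LRH1+APAP livers, Cyp7a1, Glul and Cyp2e1 are lowest in the APAP livers, and Hmox1 and Ddit3 step up from vehicle to APAP to LRH1+APAP.

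Of the 12202 genes tested with limma, 870 were higher and 631 lower in LRH1+APAP than in APAP livers, 131 and 100 of them by at least 2-fold. The 5 largest rises were in Cyp7a1 (log2 4.52, SE 0.39, adjusted p = 0.00163), Cyp2a5 (4.04, adjusted p = 0.00165), Cyp2c39 (3.66, adjusted p = 0.000258), Cyp2a4 (3.64, adjusted p = 0.00163) and Nr5a2. The 5 largest falls were in S100a8, S100a9, Snord52, Tagln and Ankrd1. The neutrophil proteins S100a8 and S100a9 fell by 3.85 and 3.71 (adjusted p = 0.0236 and 0.0268). S100a8 was at 10.4, 156.0 and 15.2 FPKM in APAP livers 1 to 3 and S100a9 at 15.9, 232.2 and 22.9 FPKM, so that APAP liver 2 carried most of both. Snord52, a small nucleolar RNA (chromosome 17, 34950951 to 34951008), fell from 108.0 ± 55.3 to 8.88 ± 8.34 FPKM (log2 -3.65, adjusted p = 0.00764, n = 3). As the libraries were made for messenger RNA, its values are uncertain. Tagln, an actin-binding protein of smooth muscle and activated stellate cells, fell from 74.9 ± 37.0 to 7.80 ± 1.80 FPKM (adjusted p = 0.00424, n = 3). Ankrd1, a target of the YAP coactivator, fell by 2.93 (adjusted p = 0.0256) from 1.66, 20.5 and 14.5 FPKM in the APAP livers. The calls of S100a8, S100a9 and Ankrd1 were lost without LRH1+APAP liver 1, 2 or 3, with adjusted p = 0.0633, 0.0818 and 0.083 for S100a8, 0.0785, 0.0843 and 0.0826 for S100a9, and 0.0711, 0.0788 and 0.0867 for Ankrd1. Without APAP liver 3, S100a9 and Ankrd1 were at 0.0503 and 0.0808.

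Pericentral genes had the smallest camera p of the 34 lists. Of 16, 14 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 1.29 that no simulated redraw of the APAP group reached among 100 (camera adjusted p = 2.39e-15, adjusted p = 0.497 with an estimated correlation). Glul, Oat and Rgn rose by 2.18, 1.40 and 1.24, and Axin2, a target of Wnt signalling, by 1.27. Of 20 genes in the cytochrome P450 list, 12 rose and 0 fell (13 and 1 adjusted over the list alone, camera adjusted p = 3.35e-08, adjusted p = 0.497 with an estimated correlation). Among them were Cyp2c54, Cyp2c50 and Cyp2e1, by 1.55, 1.54 and 0.95. Of 18 genes of conjugation and transport, 10 rose and 1 fell (13 and 2 adjusted over the list alone; camera adjusted p = 1.38e-05, adjusted p = 0.6 with an estimated correlation), among them Gstm1, Ugt1a1 and Ugt2b34 by 1.12, 0.75 and 1.15. The number that rose was 16, 6, 5, 3 and 2 without APAP liver 1, APAP liver 3 and LRH1+APAP livers 1, 2 and 3. Of 18 genes of the urea cycle and amino acid catabolism, 7 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 7.47e-05, adjusted p = 0.6 with an estimated correlation), with Tat and Oat at 1.60 and 1.40. That number was 12 without APAP liver 1, 4 without APAP liver 2, and 3 without APAP liver 3 or without any 1 of the LRH1+APAP livers. Of 14 genes of bile acid synthesis and transport, 3 rose and 0 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00262, adjusted p = 0.6 with an estimated correlation), namely Cyp7a1, Akr1d1 and Cyp27a1, the last 2 by 1.74 and 0.78. Without APAP liver 1, 9 rose. Among the 100 simulated redraws of the APAP group, the median of the list was as high in 0 for cytochrome P450, 1 for conjugation and transport, 5 for the urea cycle list and 11 for the bile acid list.

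**Figure D3:**
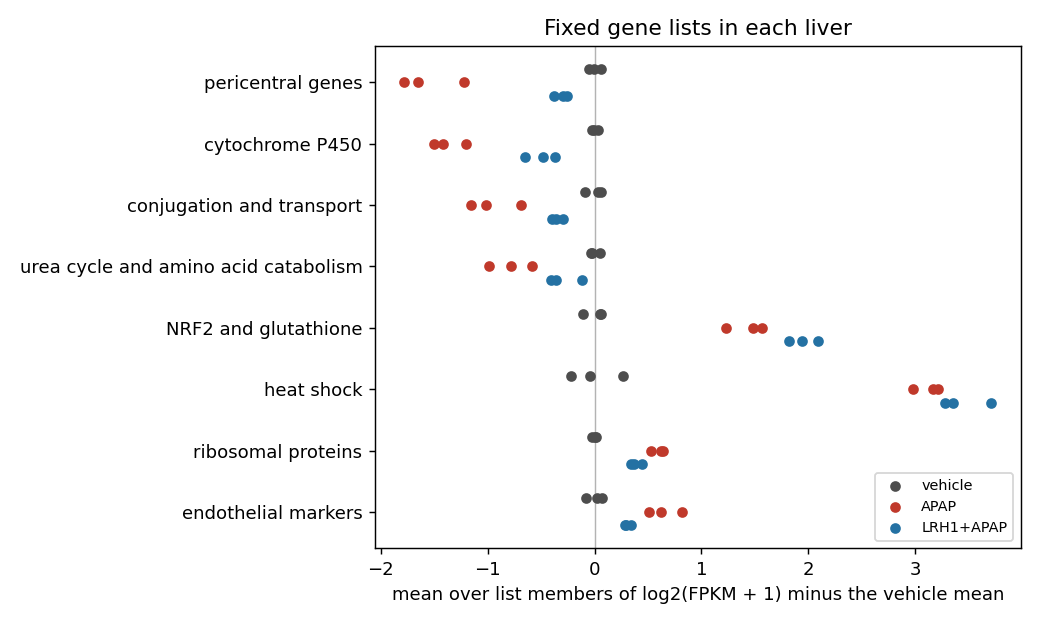
Mean over the members of 8 gene lists of log2(FPKM + 1) minus its vehicle mean, on the x axis, with 1 point per liver coloured by group. Pericentral, cytochrome P450, conjugation and urea cycle lists lie lowest in the APAP livers, NRF2 and heat shock lists lie highest in the LRH1+APAP livers, and the median LRH1+APAP minus APAP difference ranges from 1.29 for pericentral genes to -0.33 for endothelial markers.

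Lists of NRF2 and heat shock genes were higher in LRH1+APAP than in APAP livers. Of 20 NRF2 and glutathione genes, 8 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 1.66e-05, adjusted p = 0.586 with an estimated correlation). The glutathione transferase genes Gstm3 and Mgst3 rose by 2.14 and 0.88 and Hmox1 by 1.12, of which Mgst3 had fallen with APAP, from 16.7 to 8.77 FPKM, and was back at 16.9 FPKM. The count was 3 without APAP liver 3, 3 without LRH1+APAP liver 2 and 1 without LRH1+APAP liver 3. Of 12 heat shock genes, Hspb1, Dnaja1 and Hspa4l rose by 1.15, 0.65 and 0.58 and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.00327, adjusted p = 0.6 with an estimated correlation, fry adjusted p = 0.0757), and 5 rose without APAP liver 1. Of 14 circadian clock genes, Ciart and Nfil3 rose by 1.24 and 0.64 and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0141, adjusted p = 0.6 with an estimated correlation, fry adjusted p = 0.0757), while Per3 stood at 0.72 (adjusted p = 0.0549) and passed with a pseudocount of 0.1 (0.0478) and after TPM scaling (0.039), in a range of 0.039 to 0.164. The clock list lost its call without APAP liver 2 (0.0514) or LRH1+APAP liver 1 (0.0715), and 4 rose without APAP liver 1 and 0 without APAP liver 2 or 3 or LRH1+APAP liver 1 or 3. Redraws as high numbered 0 of 100 for the NRF2 list, 0 for heat shock and 2 for the clock. Other stress lists that had risen with APAP did not pass here. Of 15 immediate early genes, 1 fell and 0 rose (0 and 0 adjusted over the list alone; camera adjusted p = 0.119), with a median of -0.71, and the list passed without LRH1+APAP liver 1 (0.0126) and after TPM scaling (0.0331). The number that fell was 5 without APAP liver 1. Of 14 p53 targets, 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.58), with a median of -0.04, a mean of 0.04 and a median of 0.00883 after TPM scaling. Leaving out APAP liver 1 gave 4 that rose and 3 that fell.

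Of 20 ribosomal protein genes, 4 fell and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 3.43e-06, adjusted p = 0.6 with an estimated correlation), among them Rpl13a and Rps19 by 0.42 and 0.37. The number that fell was 16 without APAP liver 1, 1 without APAP liver 3 and 0 without LRH1+APAP liver 2 or 3. Of 14 endothelial markers, 5 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 0.0146, adjusted p = 0.6 with an estimated correlation, fry adjusted p = 0.0779). They were Pecam1, Cdh5, Lyve1, Flt1 and Eng, with Cdh5, the cadherin of endothelial junctions, at -1.33. None of the 14 fell without APAP liver 3 or any 1 of the LRH1+APAP livers, and the list call was lost without APAP liver 1 (0.0532) or APAP liver 3 (0.0686). Of 8 neutrophil markers, S100a8 and S100a9 fell and 0 rose (5 fell adjusted over the list alone; camera adjusted p = 0.00167, adjusted p = 0.6 with an estimated correlation, fry adjusted p = 0.0917), and Csf3r, the receptor of a neutrophil growth factor, stood at -1.47 (adjusted p = 0.0816) and passed without APAP liver 1 (-1.91, 0.0146) or APAP liver 2 (-0.75, 0.018), in a range of 0.0146 to 0.2. Without APAP liver 1, 7 fell, without APAP liver 2, 4 fell, and without any 1 of the LRH1+APAP livers, 0 fell. Of 12 cytokine and chemokine genes, 4 fell and 0 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.0146, adjusted p = 0.6 with an estimated correlation, fry adjusted p = 0.0828), namely Il1b, Cxcl2, Ccl2 and Ccl4 at -2.02, -2.29, -1.52 and -1.05. Without APAP liver 1, 8 fell, and without APAP liver 3 or any 1 of the LRH1+APAP livers, 2 fell. Redraws as low numbered 0 of 100 for ribosomal proteins, 0 for endothelial markers, 13 for neutrophil markers and 5 for cytokines and chemokines. Redraws of the ribosomal list spanned only -0.0971 to 0.095, a narrow range set by the 3 APAP livers.

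LRH1 targets and hepatocyte transcription factors did not pass as lists. Of 15 LRH1 targets, Cyp7a1 rose and Apoa1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.209), and 6 rose and 3 fell without APAP liver 1. Cyp8b1 was listed at 93.5 ± 33.4 and 130.5 ± 17.8 FPKM (adjusted p = 0.135; 0.00284 without APAP liver 1), and Nr0b2 at 13.3 ± 7.90 and 21.0 ± 2.93 FPKM (adjusted p = 0.218, n = 3). Of 22 hepatocyte transcription factors, Nr5a2 rose and Creb3l3 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.0726), and without APAP liver 1, 10 rose and 2 fell and the list passed (0.00998), as it did without LRH1+APAP liver 2 (0.0404) or 3 (0.0251). As Nr5a2 encodes the factor that was given, its rise and its part in the list test are not a separate response of the livers. Hnf4a stood at 0.14 (adjusted p = 0.277), Nr1h4 at 0.32 (0.587), Cebpa at -0.61 (0.689), Alb at 0.20 (0.217), Cdkn1a at -0.28 (0.596) and Saa1 at 1.54 (0.0984). Without APAP liver 2, Nr1h4 was at -0.11 and Cdkn1a at 0.000744, without LRH1+APAP liver 2 Cebpa was at 0.46, and without APAP liver 1 Saa1 passed at 1.86 (0.0411). Of 20 hepatocyte secreted protein genes, 5 fell and 0 rose (6 and 0 adjusted over the list alone; camera adjusted p = 0.188), with a median of -0.09 that was 0.00409 after quantile normalization. The number that fell was 3 without APAP liver 2, 1 without APAP liver 3, LRH1+APAP liver 1 or LRH1+APAP liver 2, and 0 without LRH1+APAP liver 3. Without APAP liver 1, 4 rose, and without APAP liver 2 the list passed (0.0488).

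Ccnd1 rose by 1.19 (adjusted p = 0.0303) and Ddit3 by 1.24 (adjusted p = 0.0256). Both calls were lost without LRH1+APAP liver 1, 2 or 3, with adjusted p = 0.0646, 0.106 and 0.084 for Ccnd1 and 0.0768, 0.0702 and 0.0895 for Ddit3, which was also at 0.0505 without APAP liver 2. The calls of Hmox1, Mgst3, Cyp27a1 and Ugt1a1 were lost without LRH1+APAP liver 3 (adjusted p = 0.0557, 0.058, 0.0533 and 0.0572). Those of Ugt2b34 and Rpl13a were lost without LRH1+APAP liver 2 (0.0511 and 0.0533) or 3 (0.0573 and 0.0549). That of Rps19 was lost without APAP liver 3 (0.0614), LRH1+APAP liver 2 (0.0717) or LRH1+APAP liver 3 (0.0759). Without APAP liver 2 or 3 or any 1 of the LRH1+APAP livers, Ciart and Nfil3 lost their calls, at up to 0.0926 and 0.13. Of the 36 genes that the rule for named genes took and that passed, 21 kept their call without each of the 6 livers in turn.

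The number of calls in this comparison varied more than in the others. Without APAP liver 1, the closest of its group to the LRH1+APAP livers on component 1, there were 2031 higher and 2607 lower genes, against 556 and 418 without APAP liver 2 and 347 and 127 without APAP liver 3. Without LRH1+APAP livers 1, 2 and 3 there were 363 and 168, 210 and 69, and 158 and 53, and a fit of the 6 libraries alone gave 203 and 60, of which 199 and 60 were among the 870 and 631. Higher genes were 58.0 percent of the calls as deposited and 76.5 percent after TPM scaling.

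The comparison of LRH1+APAP with vehicle shows how far the livers given both stood from vehicle livers. Pericentral and drug-metabolising lists were lower than in vehicle livers, and stress genes were higher. Cyp2a5 was listed at 741.6 ± 148.5 FPKM in vehicle and 723.6 ± 222.0 FPKM in LRH1+APAP livers (log2 -0.06, adjusted p = 0.901, n = 3), which does not show that the groups are equal. Glul was lower by a smaller margin than in APAP livers, at 173.3 ± 17.2 and 132.9 ± 16.5 FPKM (log2 -0.38, adjusted p = 0.0472, n = 3), and Cyp2e1 fell by 1.12 (adjusted p = 0.000392). Atf3 rose from 0.462 ± 0.0814 to 830.4 ± 107.9 FPKM (n = 3).

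Of the 12202 genes tested with limma, 4780 were higher and 979 lower than in vehicle livers, 716 and 84 of them by at least 2-fold. Nr5a2 rose by 3.14 (adjusted p = 7.74e-05). The largest rises were in Atf3 and Egr1, by 9.15 and 7.77 (adjusted p = 2.12e-08 and 2.85e-08), and in Sprr1a, at 174.3 ± 47.0 FPKM against 0 in each vehicle liver (n = 3). The largest falls were in Mup18, by 3.95 (adjusted p = 0.00618), Slc1a2, a glutamate transporter of pericentral hepatocytes, by 2.18 (adjusted p = 0.00119), and Rgs16, a regulator of G protein signalling, by 2.18 (adjusted p = 0.00148). Of the panel, Hnf4a, Nr0b2, Cyp7a1 and Cyp8b1 passed in APAP livers and not here, at -0.12, -0.35, 0.83 and -0.53 (adjusted p = 0.28, 0.527, 0.112 and 0.0723). Cyp7a1 passed without LRH1+APAP liver 1, at 1.22 (0.0291), Cyp8b1 after upper-quartile scaling (0.0238) and with 6 libraries in the fit (0.00628), and Hnf4a after upper-quartile scaling (0.0137).

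Of 16 pericentral genes, 8 fell and 1, Axin2, rose, also adjusted over the list alone (camera adjusted p = 1.19e-05, adjusted p = 0.336 with an estimated correlation, fry adjusted p = 0.0895), with a median of -0.25. Without vehicle liver 1 or LRH1+APAP liver 3, 5 fell. Of 20 genes in the cytochrome P450 list, 11 fell, also adjusted over the list alone (camera adjusted p = 3.12e-09, adjusted p = 0.264 with an estimated correlation). Of 18 genes of conjugation and transport, 9 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 1.19e-05, adjusted p = 0.313 with an estimated correlation, fry adjusted p = 0.111; 0.0602 after quantile normalization). Urea cycle and amino acid catabolism had 18 genes, of which 9 fell, also adjusted over the list alone (camera adjusted p = 3.28e-07, adjusted p = 0.287 with an estimated correlation), and 4, 5 and 4 fell without vehicle liver 1, LRH1+APAP liver 1 and LRH1+APAP liver 3. For fatty acid oxidation and ketogenesis, 13 of 18 genes fell and 1 rose (15 and 2 adjusted over the list alone; camera adjusted p = 4.14e-08, adjusted p = 0.313 with an estimated correlation, fry adjusted p = 0.0792). The number that fell was 5 without vehicle liver 2, vehicle liver 3 or LRH1+APAP liver 3 and 6 without LRH1+APAP liver 2. Of 20 nuclear genes of the respiratory chain, 12 fell, also adjusted over the list alone (camera adjusted p = 2.63e-10, adjusted p = 0.298 with an estimated correlation). The number that fell was 6, 5, 6 and 3 without vehicle livers 1 and 2 and LRH1+APAP livers 2 and 3, and 4 after TPM scaling and 20 after upper-quartile scaling. Of 15 LRH1 targets, 6 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.000465, adjusted p = 0.264 with an estimated correlation; 0.378 after quantile normalization).

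Of 12 heat shock genes, 12 rose, also adjusted over the list alone (camera adjusted p = 1.32e-09, adjusted p = 0.265 with an estimated correlation), by a median of 2.99. Of 20 NRF2 and glutathione genes, 18 rose and 0 fell (18 and 1 adjusted over the list alone; camera adjusted p = 3.03e-06, adjusted p = 0.277 with an estimated correlation). Of 20 ribosomal protein genes, 19 rose, also adjusted over the list alone (camera adjusted p = 0.000106, adjusted p = 0.339 with an estimated correlation), and 4 rose after upper-quartile scaling. Of 13 monocyte and macrophage markers, 11 rose, also adjusted over the list alone (camera adjusted p = 0.00246, adjusted p = 0.339 with an estimated correlation), while 0 of 8 neutrophil markers passed, by either adjustment (camera adjusted p = 0.422), with S100a8 at 0.688 ± 0.425 and 1.14 ± 0.206 FPKM (n = 3). Of 14 endothelial markers, 3 rose (1 adjusted over the list alone; camera adjusted p = 0.685), with a median of 0.30 that was -0.01 after quantile normalization, and 1 rose without vehicle liver 1, LRH1+APAP liver 1 or LRH1+APAP liver 3. Of 14 cell cycle genes, 9 rose, also adjusted over the list alone (camera adjusted p = 0.0411, adjusted p = 0.487 with an estimated correlation), a list call lost without vehicle liver 3 (0.0627) or LRH1+APAP liver 2 (0.0694) and after TPM scaling (0.0655).

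The number of lower genes was 610, 585, 646, 647 and 543 without vehicle livers 1 and 2 and LRH1+APAP livers 1, 2 and 3, and 1502 in a fit of the 6 libraries alone. Higher genes were 83.0 percent of the calls as deposited, 49.6 percent after upper-quartile scaling and 43.0 percent after quantile normalization, as the median difference over all genes went from 0.22 to 0.02 and -0.05; after TPM scaling that median was 0.34.

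The direction of both contrasts was compared gene by gene. Of the 7680 genes that passed in APAP against vehicle, 6130 (79.8 percent) had an LRH1+APAP minus APAP difference of the opposite sign. Because both contrasts use the APAP livers, redraws of the APAP group gave a median of 61.0 percent, with a range of 14.4 to 89.4 percent, and 33 of 100 were as high. Among genes that fell with APAP the share was 91.7 percent, against a simulated median of 66.2 percent, and 12 of 100 redraws were as high. Among genes that rose it was 76.1 percent, and 36 of 100 were as high. The covariance of the fold changes was -0.183 across genes, which are not independent replicates, against a simulated median of -0.0249, and 17 of 100 redraws were as low. Genes that fell with APAP and rose in LRH1+APAP against APAP numbered 488, against 131.5 for independent lists, and those that rose and then fell 565, against 301.7. Genes that rose in both numbered 148, against 416.0 for independent lists, and those that fell in both 9, against 95.4. Simulated redraws gave a median of 0 for each of these 4 overlaps and highest values of 2303, 4574, 490 and 145, and 5, 5, 4 and 8 of 100 redraws were as high as observed. As both contrasts share the APAP livers, the values for independent lists are not those of no change.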

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

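The tests without short transcript models and without repeated loci were chosen only after the result was seen. For APAP against vehicle, higher and lower genes numbered 3810 and 3227 after upper-quartile scaling, 3207 and 3707 after quantile normalization and 1207 and 355 at a fold of at least 2, and 3392 were higher among genes with a mean FPKM of at least 5. For LRH1+APAP against APAP they numbered 1311 and 403 after TPM scaling, 3152 and 4412 with array weights, 203 and 60 with 6 libraries in the fit, 437 and 250 at transcript level, and 131 and 100 at a fold of at least 2. Array weights gave APAP livers 1, 2 and 3 weights of 0.117, 0.175 and 29.5, so that those counts rest on a single APAP liver. Leaving out 1 liver, which leaves its group with 2 and uses a spread pooled over the groups, gave from 158 (without LRH1+APAP liver 3) to 2031 higher (without APAP liver 1) and from 53 to 2607 lower, without the same livers. For LRH1+APAP against vehicle, higher and lower genes numbered 2358 and 2396 after upper-quartile scaling, 1950 and 2580 after quantile normalization and 716 and 84 at a fold of at least 2. Lower genes numbered 626 after TPM scaling, 1616 with array weights, 1502 with 6 libraries in the fit and 543 to 689 without LRH1+APAP liver 3 and vehicle liver 3, and 2887 were higher among genes with a mean FPKM of at least 5. The model pools 1 spread per gene over groups whose root mean square SDs were 0.178 (vehicle), 0.312 (APAP) and 0.177 (LRH1+APAP). The counts of each contrast thus assume an equal spread, which these values do not show. A fit of 6 libraries leaves the third group out of that spread. The cause of these shifts was not tested. With an estimated correlation 0 lists were called in APAP against vehicle, 0 in LRH1+APAP against APAP and 0 in LRH1+APAP against vehicle.

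The share of genes with opposite signs, 79.82 percent, was 72.15 after TPM scaling, 81.85 after upper-quartile scaling, 83.61 after quantile normalization and 85.08 at a fold of at least 2, and 73.25 and 86.12 without APAP liver 2 and APAP liver 1. Signs of differences that had not passed, or of a list median, turned in a few settings. Hepatocyte secreted proteins in LRH1+APAP against vehicle passed as a lower list as deposited, with a median of -0.133, 6 of 20 that fell and 1 that rose (4 and 1 adjusted over the list alone). The camera adjusted p was 0.000111, 0.277 with an estimated correlation, and the fry adjusted p was 0.048. After quantile normalization the direction of this called list was reversed, with a median of 0.143 and no call (camera adjusted p = 0.177). For APAP against vehicle, Alb was at 0.196 after quantile normalization, Cebpa at -0.512 and 0.853 without vehicle livers 1 and 3, and Saa1 at -0.616, 0.14 and 0.0348 without APAP liver 1, APAP liver 3 and vehicle liver 3. For LRH1+APAP against APAP, Cebpa was at -1.25 and 0.463 without LRH1+APAP livers 1 and 2, Nr1h4 at 0.715 and -0.112 without APAP livers 1 and 2, and Cdkn1a at -0.614 and 0.000744 without APAP livers 1 and 2. With the replicate number as a block (replicate block), LRH1+APAP against APAP gave 508 higher and 299 lower genes, but the numbers do not pair the livers: correlations of same-numbered livers of different groups lay between -0.136 and 0.0682 over 9 pairs. Depth was not given, so no limit of detection could be set for genes near 0 FPKM.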

Other observations

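The tests of other splits of the livers, of quantile normalization, of the share of the 100 most abundant genes, of secreted protein genes, of single livers and of stress genes were chosen only after the result was seen. Genes of fatty acid metabolism moved apart between LRH1+APAP and APAP livers. Fads1 and Fads2, the desaturases that make polyunsaturated fatty acids, fell by 0.60 and 0.80 (adjusted p = 0.00626 and 0.00673), while Dgat2, Me1, Gpam and Thrsp, which act in making fat, rose by 0.85, 0.41, 0.39 and 1.57. In the list of 14 genes of fatty acid synthesis, 4 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.137), and 0 of 100 redraws of the APAP group had a list median as high. The number that rose was 1 without APAP liver 3 or LRH1+APAP liver 2, 2 without LRH1+APAP liver 1 or 3, and 6 without APAP liver 1. Mup1 and Mup3, major urinary proteins, were lower by 0.51 and 0.57.

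Single genes of the integrated stress and unfolded protein response went both ways. Trib3, Chac1 and Sesn2, targets of the integrated stress response, rose by 0.69, 0.82 and 0.57 with Atf3 and Ddit3, while Asns, Fgf21 and Xbp1 fell by 0.87, 1.59 and 0.99. Of the 18 genes of this list 5 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.519), with 6 and 5 without APAP liver 1. The numbers that rose and fell were 3 and 2 without APAP liver 2, 2 and 1 without APAP liver 3, 1 and 3 without LRH1+APAP liver 1, 2 and 0 without LRH1+APAP liver 2, and 0 and 0 without LRH1+APAP liver 3. Among 10 Kupffer cell markers Slc40a1, an iron exporter, rose by 0.86, and Fcna, Clec4f and Marco fell by 0.80, 0.37 and 1.16 (1 and 4 adjusted over the list alone; camera adjusted p = 0.052, fry adjusted p = 0.023), and 0 of 100 redraws of the APAP group had a list median as low. The number that fell was 1 without any 1 of the LRH1+APAP livers and 2 without APAP liver 2 or 3, and the list passed without APAP liver 2 (0.0465), APAP liver 3 (0.0177), LRH1+APAP liver 2 (0.0287) or LRH1+APAP liver 3 (0.0251).

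In APAP against vehicle, 76.0 percent of the calls were higher. After quantile normalization the share was 46.4 percent, but that normalization forces equal distributions on the libraries, so a true shift and a shift from scaling cannot be told apart by it. The lower share of the 100 genes of highest mean in vehicle livers gives the remaining genes a log2 gain of 0.28, beside a median of 0.25 over all genes. That gain follows by arithmetic and would also arise if the remaining genes truly rose, so it does not decide between causes. Choosing the genes as highest in vehicle livers also favours a fall elsewhere. The 100 highest genes of each library itself held 54.3 to 55.2 percent in vehicle and 48.9 to 50 percent in APAP livers. That lower abundant liver messages lift the others in a measure of shares is a candidate explanation that was not tested. Whether total messenger RNA per cell changed stays open, as no external standard is given in the sources used here.

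Pericentral genes were lower with APAP and higher again in LRH1+APAP livers. Dilution of hepatocyte RNA by other cells as the only cause is argued against by the median of 0.029 in hepatocyte secreted proteins (bootstrap SE over genes 0.17), against -1.42 in pericentral genes. Other hepatocyte lists fell by less than pericentral genes. Their medians were -0.27 for transcription factors, -0.29 for complement and coagulation, -0.45 for periportal genes and -0.78 for the urea cycle list. A part of the fall from dilution therefore stays open. One outlying liver is argued against by the lowest pericentral median of 1.19 without each of the 6 livers in turn. NRF2, heat shock and unfolded protein response genes that had risen with APAP had a median LRH1+APAP minus APAP difference of 0.3 (bootstrap SE over genes, not livers, 0.1, 27 of 39 above 0). A uniformly smaller response to APAP is argued against by the NRF2 and heat shock lists, with medians of 0.53 and 0.34, above 0. List means over vehicle were 1.82 to 2.09 in LRH1+APAP and 1.23 to 1.57 in APAP livers for NRF2. For heat shock they were 3.28 to 3.71 and 2.98 to 3.21. Although 0 of 100 redraws reached these medians, the redraws rest on the deviations of only 3 APAP livers and add little. The integrated stress and unfolded protein response list had a median of 0.04, which 33 of 100 redraws reached. Medians were -0.71 for immediate early genes, -0.04 for p53 targets, -0.70 for cytokines and chemokines and -1.68 for neutrophil markers. An action of LRH1 or of its delivery on these genes, less loss of pericentral hepatocytes and a smaller response to APAP in part of the genes stay open as hypotheses. The high share of opposite signs over all genes that passed with APAP may come in part or in whole from the shared APAP livers, as 33 of 100 redraws were as high.

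Snord52 and Rmrp, both non-coding RNAs, rose with APAP, Rmrp from 2.03 ± 1.41 to 31.1 ± 23.0 FPKM (n = 3). A general gain of RNA under 200 bases is argued against, since tested transcripts of that size had a median only 0.14 above that of all genes. The hypothesis that snoRNA host genes were higher as a group was met, with 13 of 16 that rose, where 5835 of all 12202 genes did. Their median was 0.83, at percentile 99.95 of 10000 expression-matched random lists, which draw genes and not livers. In LRH1+APAP against APAP the median of the host genes was -0.26, and 11 of 100 redraws of the APAP group were as low. For Snord52, altered snoRNA processing and a change in transcription of the hosts both stay open, as neither was tested. The host gene list does not bear on Rmrp, and whether it holds the host of Snord52 was not examined. As the libraries were made with a messenger RNA kit, the FPKM of such short RNAs may not follow their true levels.

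Tagln, Ankrd1 and Thbs1 were lower in LRH1+APAP than in APAP livers, and 19 other SRF and YAP targets had a median of -0.81 at percentile 0 of the random lists. Their number that fell was 3, against 15 without APAP liver 1, 2 without vehicle liver 1 or 3, 1 without vehicle liver 2, APAP liver 2 or LRH1+APAP liver 2, and 0 without APAP liver 3, LRH1+APAP liver 1 or LRH1+APAP liver 3. As 15 of 100 redraws of the APAP group were as low, an effect of LRH1 and the spread of the APAP livers cannot be told apart with 3 livers. Tat, Tsc22d3 and Klf15, which glucocorticoids induce, were higher, while 15 other glucocorticoid targets had a median of 0.12 at percentile 92.08, and 28 of 100 redraws were as high. That percentile was not taken as excluding the idea because 6 of the 15 had been looked at in other lists, and the remaining 9 had a median of 0.40 at percentile 99.86, computed after the first value was seen. Without APAP liver 1 that median was 0.19, so an effect on this pathway and the spread of the APAP livers cannot be told apart.

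For each comparison, 3 livers against 3 give 10 splits, too few for a share under 0.05. Every other split mixes livers of both groups, which moves the group difference into the spread. Few calls in those splits therefore follow from any large difference along the real split, and their low counts decide nothing. Only the real split, 1 of 10, reached the real number of calls in APAP against vehicle (7680, highest other 1). The same number, 1 of 10, held in LRH1+APAP against APAP (1501, highest other 2) and, again 1 of 10, in LRH1+APAP against vehicle (5759, highest other 2).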
